A study of Mus musculus with 12 samples.

How the data were processed

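RNA was taken from the distal 0.5 cm of sciatic nerves of C57Bl6 mice aged about 2 months, after a crush of 30 s, per the labels' protocols. Total RNA of 6 mice was pooled per sample, amplified and labelled with the dye Cy3, and each pool was hybridised to 1 array. The labels name the pools biological replicates of their time point, so the p-values measure the spread between arrays of one time point. The arrays lay on 3 slides. Within day 0, day 3 and day 7 that spread held differences between slides as well as between pools. Within day 14, on slide 3 alone, it held no difference between slides. Samples were grouped by the time after injury in the labels, with 3 pools at each of 4 time points.

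The scanner files hold spot intensity values made by the authors with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.1.1 per the file headers. The processed intensity is background-subtracted and detrended within an array and is not normalized between arrays, per the file headers. The deposited series table holds log2 values. Its columns all had a median of 6.42 and identical quartiles, as quantile normalization gives, and correlated at 0.993 to 1.000 with the log2 of the matching scanner signal, with slopes of 0.953 to 1.04. Its scale and direction thus follow from the scanner files, no probe was centred, and the exact steps behind it are not given in the sources used here.

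From the scanner files, control spots and spots flagged as outliers were left out, which left 25 probe values missing. The log2 processed signals of repeated spots were averaged, for 85274 probes with 2 spots and 5478 with 1. Each array was scaled to a common 75th percentile, set to the arrays' mean of 9.34. On the median array 66.9% of probes were well above background, so the percentile was taken over all probes. A probe was tested if it was well above background on all 3 arrays of at least 1 time point. Limma 3.58.1 in R 4.3.3 fitted 1 mean per time point over all 12 arrays (8 residual degrees of freedom), and moderated tests gave 6 comparisons and an F test. A probe was called at a Benjamini-Hochberg adjusted p below 0.05. Where a probe was seen on no array of 1 group, a lower bound was formed: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

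On simulated data with the real levels and spread, 62803 probes and 50 changed probes per size, the fit of day 3 against day 0 recovered 4% of log2 changes of 0.5, 64% of those of 1, 96% of those of 2 and 100% of those of 4. It made 10 false calls among 142. For day 7 against day 0 the shares were 0%, 62%, 94% and 100%, and for day 14 against day 0 they were 4%, 60%, 94% and 100%. The simulated arrays held no slide effect and far fewer changed probes than the real data, where 27909 were called for day 3 against day 0. The shares and false calls hold for that simulated setting only. The finder of overlapping probes was tested on made-up sequences.

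Overlap between probes was defined as at least 25 shared bases on the same strand, and connected probes formed a family. A total of 76635 probes overlapped no other and 14117 formed 4905 groups, 27 of them with 20 or more probes. Families were tested with limma's camera, with its preset correlation and an estimated one, and with fry, adjusted over 80 tests. Python 3.11.15, pandas 2.3.3 and networkx 3.6.1 were used for reading and for families.

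Slide was read from the files as a batch. The replicate numbers of day 0 and day 3 coincided with shared slides, and the deviations of all 3 same-number pairs of these days from their group means were correlated (0.325, 0.449 and 0.590), as were those of replicates 1 and 2 across numbers on slide 1 (0.347 and 0.408). Alternatives fixed before the data were examined were quantile normalization, another set of probes for the percentile, normexp background correction with an offset of 50, other filters on dim probes, the authors' log2 values, slide as a fixed and as a random block, fits within slides, the replicate number as a block, array weights, a variance trend, only the arrays compared, stricter thresholds and leaving out each array. The rule for named probes was also fixed then: the largest rises and falls among called probes that were well above background and unsaturated on all 6 arrays, with no overlap between the groups. It asked for genes with symbols and for up to 10 in each direction. Since the probe IDs have no names in the files, it was applied to probes and limited to 2 rises and 2 falls per comparison, and extended to day 14 against day 3. A probe that met the rule for day 14 against day 3 is not reported here. The planned gene lists, the genes to be named in every case and the counts of non-coding probes need gene names and were not run. Families of overlapping probes, the counts of probes with opposite directions at day 3 and day 14, the family tests with the replicate block, the simulation with correlated slides, and the values with slide as a fixed block for probes sorted by the day of their largest difference, changed at day 3 or called in several comparisons, were chosen after the data were seen.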

Results

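The series measured RNA in the distal part of the mouse sciatic nerve after a crush, on 12 one-colour arrays that carry 90752 probes of 60 bases. The labels give 4 time points: day 0, day 3, day 7 and day 14 after the injury. Each time point had 3 arrays, and each array held RNA pooled from 6 mice, so that 18 mice stood behind each time point and 72 behind the series. The crush of a peripheral nerve cuts its axons and leaves the outer sheath in place, and the distal segment is where the cut axons degenerate and new ones grow in. The question in the series title is how the RNA of this distal segment, long non-coding RNA in particular, differs over time.

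The files do not pair probe IDs with gene names, so probes are reported by ID and sequence. The RNA each probe reads, its place in the genome and whether that RNA is coding were not analysed here. At most 2 probes that rose and 2 that fell are named per comparison.

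Between 64.2% and 79.5% of the spots of an array were well above background, and no spot was saturated. The share was 73.7% to 79.5% on slide 1, 66.7% to 71.5% on slide 2 and 64.2% to 67.5% on slide 3. Slide 1 held 2 arrays of day 0 and 2 of day 3. Slide 2 held 1 array of day 0, 1 of day 3 and 2 of day 7. Slide 3 held 1 array of day 7 and all 3 of day 14. A total of 62803 probes were tested, and 52853 probes were well above background on all 12 arrays. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.16.

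Arrays of one time point resembled one another more than arrays of different time points in most pairs. Pearson correlations across probes, which are not independent replicates, ran from 0.985 to 0.995 within day 0, 0.981 to 0.996 within day 3, 0.991 to 0.994 within day 7 and 0.994 within day 14. Between day 0 and day 3 they ran from 0.925 to 0.946, and between day 0 and day 14 from 0.944 to 0.967. Day 7 and day 14 were closest, at 0.978 to 0.987. The day 7 array on slide 3, the slide of all day 14 arrays, gave 0.986 to 0.987 with them. The day 7 arrays on slide 2 gave 0.978 to 0.9845, so the shared slide may have raised the highest values. The first principal component held 46.7% of the variance and set the day 0 arrays, at -169 to -154, apart from all others, at 2.18 to 111.53. The second held 32.8%. On it the day 0 array of slide 2 lay at -36.9, away from the day 0 arrays of slide 1 at 57.2 and 57.4, so this component also followed the slides.

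**Figure D1:**
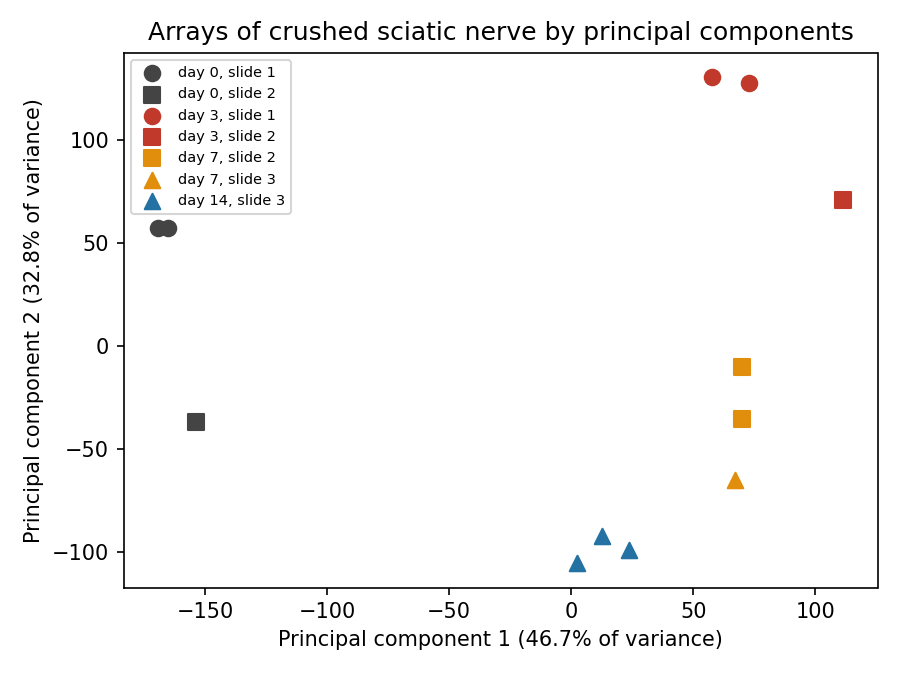
Each point is 1 array, placed by its first principal component (horizontal axis, 46.7% of the variance) and second (vertical axis, 32.8%), with colour for the day and shape for the slide. Day 0 arrays lie at the left, day 3 arrays at the upper right and day 14 arrays at the bottom, and the day 0 and day 3 arrays of slide 2 lie below those of slide 1.

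The F test over all 4 time points called 44660 of the 62803 probes. Of these, 18608 differed from day 0 by 2-fold or more on at least 1 day.

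Day 3 was compared with day 0 to show the early response to the crush. By day 3, 13652 probes rose and 14257 fell, which together were 44.4% of those tested. A change of 2-fold or more was seen for 5378 probes that rose and 6389 that fell. A change of 8-fold or more was seen for 827 and 764, and of 32-fold or more for 115 and 86. Among the probes well above background on all 6 arrays, the largest rise was that of MOUSELNCRNA_19069 (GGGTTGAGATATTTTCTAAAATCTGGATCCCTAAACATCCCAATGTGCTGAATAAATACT). Its log2 signal went from 5.90 ± 0.47 (SD, n = 3) at day 0 to 15.18 ± 0.80 (SD, n = 3) at day 3. That is a log2 fold change of 9.28 (SE 0.46, limma adjusted p = 8.76e-08), or 620-fold. MOUSELNCRNA_61577 (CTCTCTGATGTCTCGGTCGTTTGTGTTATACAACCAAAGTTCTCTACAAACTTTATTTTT) rose by 9.17 (SE 0.23, limma adjusted p = 5.62e-09) from 4.88 ± 0.18 (SD, n = 3). Among the falls, MOUSELNCRNA_63345 (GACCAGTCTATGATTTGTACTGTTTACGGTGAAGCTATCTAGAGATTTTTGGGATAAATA) went from 15.80 ± 0.04 (SD, n = 3) to 8.86 ± 0.64 (SD, n = 3), a change of -6.94 (SE 0.36, limma adjusted p = 1.28e-07).

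MOUSELNCRNA_66483 (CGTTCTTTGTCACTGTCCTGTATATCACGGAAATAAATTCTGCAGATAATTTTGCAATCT) also met the rule for named falls, at -6.67 (SE 1.88, limma adjusted p = 0.0134), but varied widely within every time point. Its log2 signal on the 3 day 0 arrays was 16.26, 9.82 and 14.92, on the day 3 arrays 5.89, 5.82 and 9.27, on the day 7 arrays 13.39, 7.69 and 10.19, and on the day 14 arrays 14.43, 13.80 and 10.51. Without day 0 replicate 1 its limma adjusted p was 0.0565, with a change of -5.38.

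A further 378 probes that rose at day 3 were well above background on all 3 day 3 arrays and on no day 0 array, and 80 of them rose at least 8-fold by a lower bound. In the other direction, 719 probes that fell were well above background on all day 0 arrays and on no day 3 array, 46 of them with a bound of at least 8-fold. Both days lay on slides 1 and 2. The count with slide as a fixed block was 35138, of which 17588 rose and 17550 fell. Within slide 1 it was 29770. Within slide 2, which held 1 array of each day, it was 16362, with a spread that came from the 2 day 7 arrays alone and was assumed for the single arrays of day 0 and day 3.

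Day 7 was compared with day 0 to show the response 1 week after the crush. At day 7, 12840 probes rose and 15075 fell, or 44.4% of those tested, and 4527 and 5882 did so by 2-fold or more. MOUSELNCRNA_69499 (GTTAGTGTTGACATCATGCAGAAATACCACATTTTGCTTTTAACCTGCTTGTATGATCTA) rose by 7.53 on the log2 scale (SE 0.20, limma adjusted p = 6.87e-09), from 5.09 ± 0.11 to 12.63 ± 0.30 (SD, n = 3 each). MOUSELNCRNA_61577, named above for day 3, was still 7.05 above day 0 (SE 0.23, limma adjusted p = 1.83e-08). Among the probes well above background on all 6 arrays, the largest fall was that of MOUSELNCRNA_58744 (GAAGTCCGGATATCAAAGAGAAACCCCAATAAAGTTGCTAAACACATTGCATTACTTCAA), from 13.88 ± 0.11 to 6.11 ± 0.53 (SD, n = 3 each), a change of -7.77 (SE 0.29, limma adjusted p = 3.85e-08). The next, MOUSELNCRNA_77066 (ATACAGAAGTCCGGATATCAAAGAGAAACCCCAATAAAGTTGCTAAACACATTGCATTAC), overlaps it in sequence and changed by -7.74 (SE 0.31, limma adjusted p = 4.97e-08), so the pair is not independent.

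Probes that rose and were seen on all arrays of day 7 and on none of day 0 numbered 363. Those that fell and were seen on all arrays of day 0 and none of day 7 numbered 1019. The lower bound was over 2-fold for 615 of these 1019, over 8-fold for 65, and at most 261-fold. Of the 363 rises, 332 had a bound over 2-fold. Slide 1, with the highest shares of spots well above background, held day 0 arrays and no day 7 array. These counts may thus also hold a difference between slides, which was not tested for them. Quantile normalization gave 28504 called probes, of which 55.2% rose, against 46.0% under the main scaling. The fit with slide as a fixed block called 23560 probes, with 10554 that rose and 13006 that fell, and within slide 2, with 1 array of day 0, it was 11817.

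Day 14 was compared with day 0 to show what remained 2 weeks after the crush. At day 14, 12214 probes rose and 18191 fell, or 48.4% of those tested, and 3499 and 7409 did so by 2-fold or more. Changes of 8-fold or more were fewer than at day 3, with 366 that rose and 271 that fell. MOUSELNCRNA_33322 (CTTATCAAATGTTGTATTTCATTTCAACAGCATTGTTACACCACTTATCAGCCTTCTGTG) rose by 6.45 on the log2 scale (SE 0.37, limma adjusted p = 1.04e-06), with means of 5.53, 6.98, 10.55 and 11.98 at day 0, day 3, day 7 and day 14. MOUSELNCRNA_19069, named above for day 3, was 6.25 above day 0 (SE 0.46, limma adjusted p = 4.09e-06). MOUSELNCRNA_56176 (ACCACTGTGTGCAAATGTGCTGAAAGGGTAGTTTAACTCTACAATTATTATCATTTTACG) fell to 6.23 ± 0.97 from 12.68 ± 0.10 (SD, n = 3 each), a change of -6.45 (SE 0.44, limma adjusted p = 2.89e-06). MOUSELNCRNA_19351 (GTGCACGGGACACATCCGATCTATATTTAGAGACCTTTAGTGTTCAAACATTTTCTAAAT) changed by -6.23 (SE 0.28, limma adjusted p = 3.30e-07).

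Day 14 shared a slide with day 7 only, so no slide holds both day 14 and day 0. With slide as a fixed block, which links the days through a single day 7 array, 10379 probes were called, with 4163 that rose and 6216 that fell. Of these, 8961 were called in the same direction without the block. With slide as a random block the count was 15612. The split between rises and falls also moved with the scaling: 40.2% of the called probes rose under the main scaling and 53.3% under quantile normalization, and the median log2 fold change of all tested probes was -0.13 under the first and 0.01 under the second. Where the surplus of falls lay depended on the slide term. Without it, 1959 of the 15701 dimmest probes tested rose and 5994 fell, and 3265 of the 15701 brightest rose and 3688 fell. With slide as a fixed block, 814 of the dimmest rose and 1164 fell, and 976 of the brightest rose and 2138 fell.

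**Figure D2:**
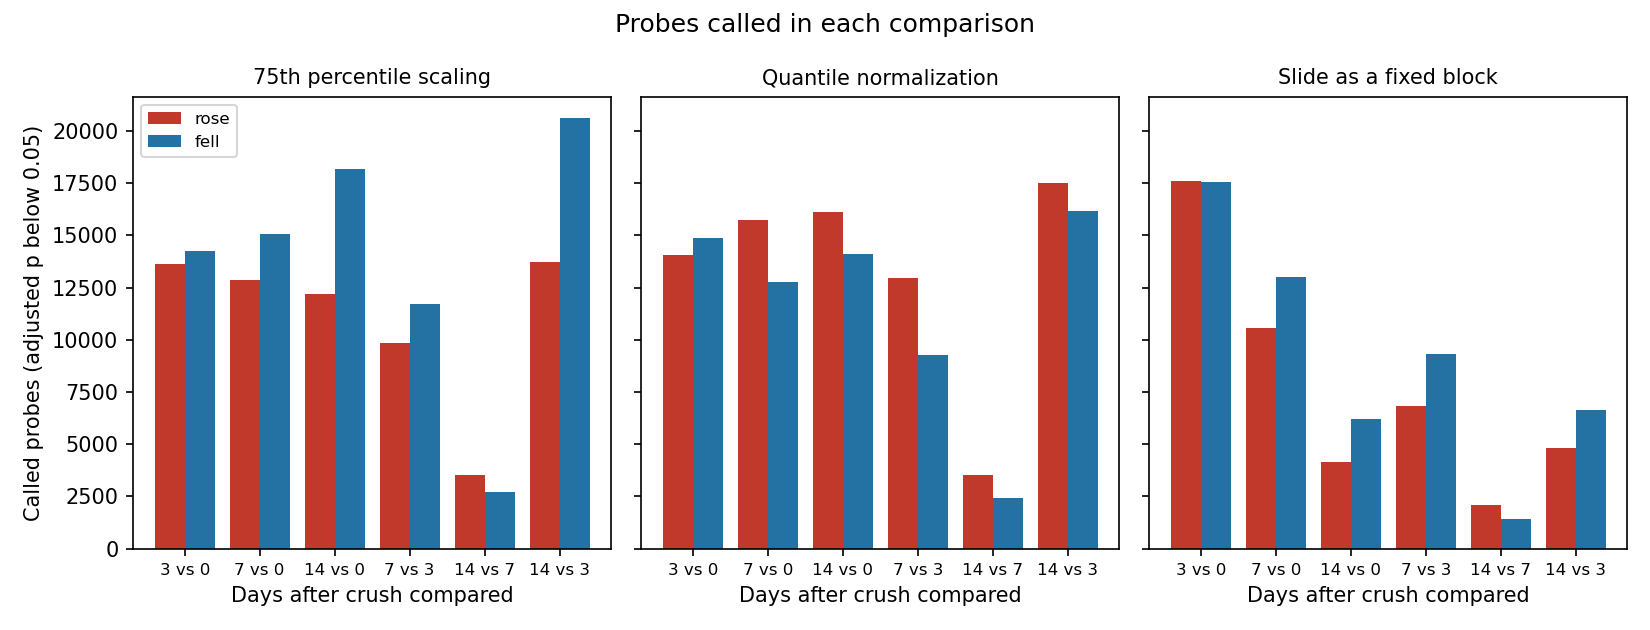
Bars give the number of probes called at an adjusted p below 0.05 in each of the 6 comparisons, red for rises and blue for falls, under the 75th percentile scaling, quantile normalization and the fit with slide as a fixed block. For day 14 against day 0 the bars are 12214 and 18191 under the first, and 4163 and 6216 under the third, and rises exceed falls under the second.

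**Figure D3:**
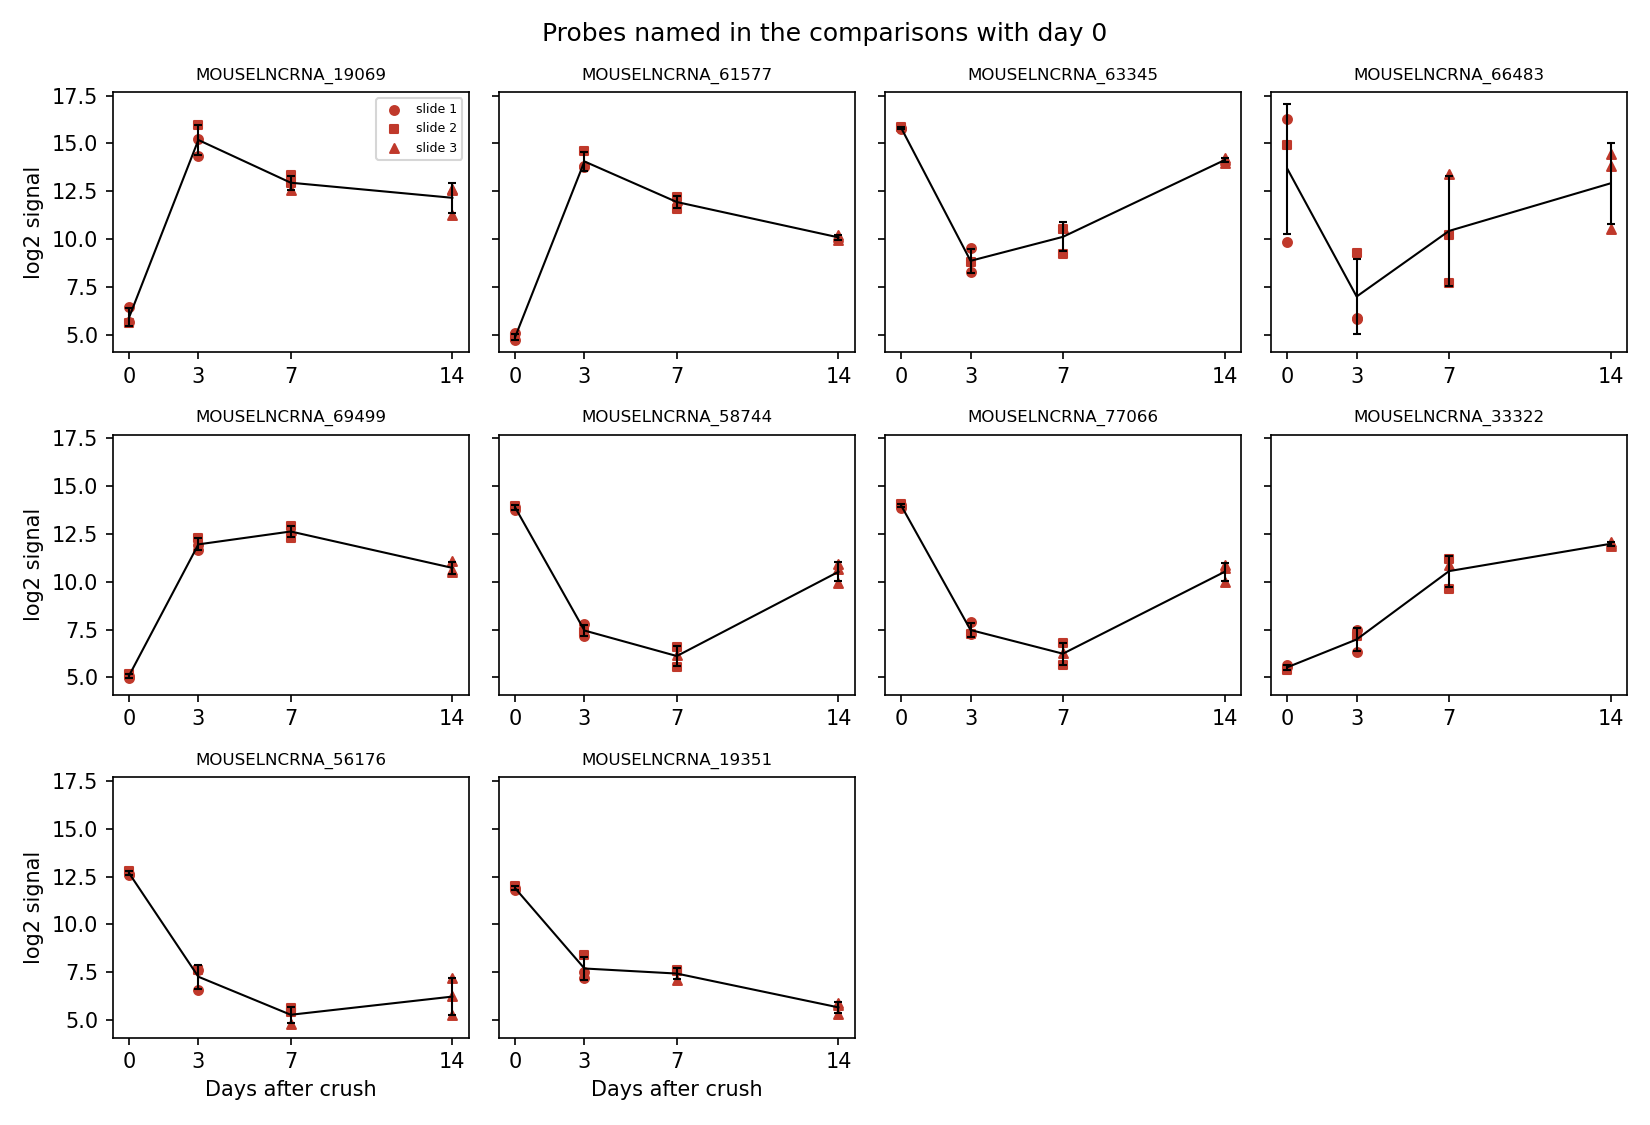
Each panel shows 1 probe named in the comparisons with day 0, with log2 signal on the vertical axis and days after the crush on the horizontal axis. Points are arrays with shape for the slide, the line joins the means and bars are SD (n = 3); MOUSELNCRNA_66483 shows the widest spread, with an SD of 3.40 at day 0.

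The later days were compared with one another to follow the course of the response. From day 3 to day 7, 9836 probes rose and 11697 fell, and 2178 and 3061 did so by 2-fold or more. MOUSELNCRNA_15618 (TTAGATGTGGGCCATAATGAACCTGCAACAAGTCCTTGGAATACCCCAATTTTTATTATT) rose by 3.89 (SE 0.18, limma adjusted p = 2.19e-06), from a mean of 6.33 at day 3 to 10.22 at day 7. MOUSELNCRNA_56339 (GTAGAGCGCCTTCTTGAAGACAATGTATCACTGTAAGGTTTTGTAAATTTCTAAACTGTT) stood at 8.01 at day 0, 4.92 at day 3 and 8.76 at day 7, a rise of 3.83 from day 3 (SE 0.22, limma adjusted p = 6.82e-06). MOUSELNCRNA_67566 (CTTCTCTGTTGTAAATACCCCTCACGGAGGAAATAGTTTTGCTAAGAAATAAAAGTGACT) was not well above background on any day 0 or day 14 array, had a mean of 11.68 at day 3 and changed by -5.71 to day 7 (SE 0.22, limma adjusted p = 6.60e-07). MOUSELNCRNA_53345 (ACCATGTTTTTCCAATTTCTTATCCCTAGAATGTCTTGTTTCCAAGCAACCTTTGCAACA) changed by -4.75 (SE 0.54, limma adjusted p = 0.000253). Under quantile normalization 58.3% of the called probes rose, against 45.7% under the main scaling. The count of 21533 fell to 12088 without day 3 replicate 1, 12180 without day 7 replicate 1 and 13724 without day 7 replicate 3, of which 53.4%, 53.4% and 51.1% rose, and 51.5% rose without day 3 replicate 2. A total of 16182 probes were called with slide as a fixed block and within slide 2, with 1 array of day 3, 4913.

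From day 7 to day 14, 3521 probes rose and 2733 fell, or 9.96% of those tested, and 1274 and 733 did so by 2-fold or more. MOUSELNCRNA_79568 (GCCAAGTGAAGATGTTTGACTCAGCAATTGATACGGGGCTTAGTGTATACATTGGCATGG) rose by 4.53 (SE 0.25, limma adjusted p = 6.07e-06), with means of 8.58, 10.26, 7.06 and 11.59 at day 0, day 3, day 7 and day 14. MOUSELNCRNA_58744, named above for its fall at day 7, rose again by 4.40 (SE 0.29, limma adjusted p = 1.45e-05) to 10.52, still below its day 0 level of 13.88. MOUSELNCRNA_76825 (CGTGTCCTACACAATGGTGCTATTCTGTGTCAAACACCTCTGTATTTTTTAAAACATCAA) changed by -3.27 (SE 0.20, limma adjusted p = 1.02e-05). MOUSELNCRNA_88135 (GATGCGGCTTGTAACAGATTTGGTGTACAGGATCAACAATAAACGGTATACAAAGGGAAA) changed by -3.72 (SE 0.70, limma adjusted p = 0.00751), and with slide as a fixed block it changed by -3.24 with a larger error (SE 0.97, limma adjusted p = 0.101), which was not called. The count was 3477 with slide as a fixed block. Within slide 3, which held 1 day 7 array, it was 820, with a spread that came from the 3 day 14 arrays alone. It fell to 3677 without day 7 replicate 2, 3663 without day 7 replicate 3, 3529 without day 14 replicate 1 and 3559 without day 14 replicate 2.

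From day 3 to day 14, 13736 probes rose and 20619 fell, and 4066 and 8114 did so by 2-fold or more. MOUSELNCRNA_49078 (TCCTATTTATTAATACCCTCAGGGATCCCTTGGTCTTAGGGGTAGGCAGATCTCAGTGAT) stood at 11.12 at day 0, 7.01 at day 3 and 12.76 at day 14, a rise of 5.75 from day 3 (SE 0.37, limma adjusted p = 1.85e-06). MOUSELNCRNA_66483, named above for its wide spread, changed by 5.92 (SE 1.88, limma adjusted p = 0.0219), and by -0.29 with slide as a fixed block (SE 3.16, limma adjusted p = 0.964). MOUSELNCRNA_53345, named above for day 7, fell from 11.03 ± 1.40 to 5.31 ± 0.33 (SD, n = 3 each), a change of -5.72 (SE 0.54, limma adjusted p = 2.11e-05). A total of 11457 probes were called with slide as a fixed block and as a random block 18048, and 52.0% of the called probes rose under quantile normalization against 39.98% under the main scaling.

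The large early changes were smaller at day 14 in the median probe. Of the 5378 probes that rose 2-fold or more at day 3, 3788 (70.4%) were called lower at day 14 than at day 3, 229 were called higher and 1361 were not called. The median probe of this set kept 72.9% of its day 3 change at day 7 and 51.1% at day 14, and 3777 were still called above day 0. Of the 6389 that fell 2-fold or more, 4280 (67.0%) were called higher at day 14 than at day 3, and the median probe kept 73.3% of its change at day 7 and 48.0% at day 14. With slide as a fixed block, 2526 (47.0%) of the first set were called lower at day 14 than at day 3 and 2286 (35.8%) of the second were called higher, and the median probe kept 49.9% and 53.3% of its change at day 14. Of the rises, 2307 were still called above day 0 with the block. Because these probes were chosen for a large day 3 value, part of the shrinkage would arise from that choice alone.

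Probes called by the F test that changed 2-fold or more were sorted by the day of their largest difference from day 0. Only probes also called against day 0 on that day were kept. No test asked whether that day differed from the other later days. By this choice alone the median of each set is largest on its own day. Rises were largest at day 3 for 3835 probes, at day 7 for 2062 and at day 14 for 1105. Falls were largest at day 3 for 4422, at day 7 for 2408 and at day 14 for 4548. The last set was near its day 0 level at day 3, with a median log2 fold change of -0.07, and reached -0.93 at day 7 and -1.35 at day 14. This late set depended on the slide term: with slide as a fixed block, its medians were -0.20 at day 7 and -0.38 at day 14, and 806 of its 4548 probes were called below day 0 at day 14. The rises that were largest at day 14 had a median of 1.53 without the block and 1.35 with it, and 757 of the 1105 were called with it.

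A total of 6618 probes were called above day 0 on all 3 later days and 6675 below it, and 2253 and 2394 of them were so by 2-fold or more each time. The counts with slide as a fixed block were 3235 above and 4817 below, of which 2919 and 3822 were also called without the block. The fold changes against day 0 were correlated across probes: r = 0.79 between day 3 and day 7, 0.59 between day 3 and day 14 and 0.87 between day 7 and day 14. The 3 comparisons share the day 0 arrays, and unchanged groups simulated against such shared controls gave r = 0.50. The covariances were 0.80, 0.53 and 0.73, against a simulated covariance of 0.03. That simulation held no slide effect. With simulated arrays of one slide correlated at 0.56, as estimated, r was 0.33 between day 3 and day 7, 0.25 between day 3 and day 14 and 0.59 between day 7 and day 14, and the covariances were 0.02, 0.02 and 0.06. Day 3 and day 14 shared 7022 rises, where independent lists would share 2655, and 7314 falls, where independent lists would share 4130. In the fit with slide as a fixed block they shared 3316 rises, where independent lists would share 1166, and 4935 falls, where independent lists would share 1737. Part of each excess may come from the shared day 0 arrays, which are too few to split.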

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

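All results in this part were chosen after the data were seen, and the tests of the family of overlapping probes, other than that of brightness and GC content, were written before their results were known.

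A difference between time points was found for 607 probes that were called above day 0 at day 3 and below it at day 14, with the difference between day 14 and day 3 itself called. In the opposite order, 962 probes were called below day 0 at day 3 and above it at day 14. Both sets were small beside the 7022 rises and 7314 falls that day 3 and day 14 shared. How many opposite calls independent lists would give was not computed. Of the first set, 98 differed by 2-fold or more on both days. The counts depend on slide: with slide as a fixed block they were 302 and 215, and under quantile normalization 504 and 1265. Single arrays moved them too. The first count was 344 without day 0 replicate 1, 310 without day 0 replicate 2, 1049 without day 3 replicate 3, and 385, 398 and 383 without day 14 replicate 1, 2 and 3. The second was 541 without day 0 replicate 1, 500 without day 0 replicate 2 and 637 without day 14 replicate 3.

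A family of 127 probes linked by overlapping sequence, with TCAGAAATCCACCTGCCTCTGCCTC as its most shared stretch, rose at day 3. It was chosen as the tested family with the most members called up at day 3. That rise is therefore no independent support, and part of the later decline would arise from the choice alone. The family's median log2 fold change at day 3 was 0.60, with 115 members called up and 1 called down. Its median was 0.31 at day 7 and 0.07 at day 14, and the change from day 3 to day 14 had a median of -0.53, with 90 members called down and 0 called up (fry adjusted p = 0.0285; camera adjusted p = 0.979 with an estimated correlation). With slide as a fixed block the medians were 0.27 at day 7, 0.26 at day 14 and -0.35 from day 3 to day 14, so how near the family came to its day 0 level at day 14 depended on the slide term. Against other probes at day 3, camera with its preset correlation gave an adjusted p = 1.35e-10, and adjusted p = 0.979 with an estimated correlation, since the members move together at an estimated correlation of 0.77. The fry adjusted p at day 3 was 0.0285, and with the replicate block it was 0.114, adjusted over 20 tests, with 106 members called up. The median stayed above 0 under each scaling: 0.51 under quantile normalization and 0.57 under normexp.

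Several explanations were weighed for the rise of this family at day 3. The values argue against a constant difference between slides, since each day had 2 arrays on slide 1 and 1 on slide 2. The family median was 0.43 within slide 1 and 0.93 within slide 2, the lower being 0.431. The slide 2 value compares 1 array with 1 array, and the gap between the slides was not tested. Brightness and GC content stay open: the family exceeded probes matched on both by 0.39 more at day 3 than at day 0, and the lowest day 3 array lay above the highest day 0 array by 0.154, less than the SD between arrays of 0.17. Reading of 1 pooled RNA by every probe stays open: the third with the fewest partners exceeded the third with the most by 0.0374 (bootstrap interval -0.04 to 0.07), and probes that read 1 RNA would also rise alike, so that a difference near 0 does not count against it, although it was set as the bound before the value was known. The time after injury also stays open as an explanation, and with 3 pools per day and an array spread of 0.44 to 0.90 at day 3 it remains a hypothesis.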

How the results depend on the processing

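Signal over background limits the dim probes, whose direction moved with scaling and slide. The counts at day 14 with slide as a fixed block rest on 1 day 7 array for their link to other slides. Of 619 recomputed values of named probes, 608 kept direction and call, 10 kept the direction without the call and 1 changed direction: MOUSELNCRNA_66483, day 14 against day 3, was -0.29 with slide as a fixed block (SE 3.16), against 5.92. It was 2.70 with slide as a random block (adjusted p = 0.437) and 1.56 with replicate block and slide (0.786). Without day 3 replicate 1, day 3 replicate 2, day 14 replicate 1 and day 14 replicate 2 it stayed at 5.37, 5.33, 5.16 and 5.47 but was not called (limma adjusted p = 0.0698, 0.0688, 0.0713 and 0.0666). Of the other counts of called probes, 162 alternative values lay within 1.5 times. Except where stated, the cause was not tested.

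For day 3 against day 0 (27909), the count was 16362 within slide 2 and 11767 at 2-fold or more, and the share that rose (48.9%) was 53.7% under normexp, 50.98% over probes seen on all 12 arrays and 50.1% with slide as a fixed block. For day 7 against day 0 (27915), it was 11817 within slide 2, 42754 with array weights, 10409 at 2-fold and 18319 at an adjusted p below 0.01, and the share that rose (46.0%) was 55.2% both under quantile normalization and in the authors' values. For day 14 against day 0 (30405), it was 10379 with slide as a fixed and 15612 as a random block, 6622 with replicate block and slide together, 10908 at 2-fold and 16829 at 0.01, and the share that rose (40.2%) was 53.3% both under quantile normalization and in the authors' values.

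For day 7 against day 3 (21533), the count was 4913 within slide 2, 8985 with replicate block and slide, 38010 with array weights, 33580 with day 0 and day 3 on slide 1 only, 5239 at 2-fold and 8702 at 0.01. Its share that rose (45.7%) was 58.3% both under quantile normalization and in the authors' values, 53.3% with the percentile over probes seen on all arrays, 55.6% within slide 2 and 54.6% at 0.01. For day 14 against day 7 (6254), the count was 3477 with slide as a fixed block, 820 within slide 3, 1445 with replicate block and slide, 13565 with array weights, 12677 with day 0 and day 3 on slide 1 only, 2007 at 2-fold and 2677 at 0.01. Its share that rose (56.3%) was 46.8% with array weights and 49.7% on the arrays compared alone, and 70.2% with replicate block and slide and 67.2% at 0.01. For day 14 against day 3 (34355), the count was 11457 with slide as a fixed and 18048 as a random block, 5654 with replicate block and slide, 12180 at 2-fold and 21069 at 0.01, and the share that rose (39.98%) was 52.0% both under quantile normalization and in the authors' values. The F test called 44660, and 18608 at 2-fold. Fits within slide 2 or 3 use fewer arrays, with a spread from 1 day alone, and stricter thresholds take fewer probes by construction. The setting of slide 1 only was chosen after seeing the data, since the slide 2 arrays of day 0 and day 3 had the lowest array weights, 0.186 and 0.163.

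Leaving out single arrays gave 24554 to 27526 for day 3, 21349 to 34952 for day 7 and 20330 to 35259 for day 14 against day 0, 12088 to 27869 for day 7 against day 3, 3529 to 8656 for day 14 against day 7, 26300 to 37030 for day 14 against day 3 and 38382 to 47713 for the F test. For day 7 against day 3 the share that rose ran from 39.0% to 53.4%. Deviations correlated above 0.1 in 5 of 18 same-number pairs (-0.297 to 0.590). Day 0 and day 3 pairs shared slides. With the replicate block the counts were 27868, 29333 and 31746 for day 3, day 7 and day 14 against day 0, 23978 for day 7 against day 3, 5754 for day 14 against day 7 and 35268 for day 14 against day 3, and no call of a named probe changed. The counts of probes with opposite directions at day 3 and day 14 (607 and 962) were 341 and 460 with slide as a random block, 85 and 125 with replicate block and slide, and 3092 and 2773 with array weights. Gene list and non-coding alternatives were not run.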

Other observations

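Families of overlapping probes were chosen after the data were seen, and differences between families were not tested. A family of 31 bright probes (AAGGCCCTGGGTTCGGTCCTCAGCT) fell on every day, with all 31 called down at day 3, day 7 and day 14 and medians of -1.04, -1.29 and -1.09. Its fry adjusted p was 0.00144, 0.000678 and 0.000896, and camera gave an adjusted p = 0.979 with an estimated correlation each time. The medians were -1.24, -1.27 and -0.95 under quantile normalization and -1.04, -1.61 and -1.38 with slide as a fixed block. At day 3 they were -1.14 within slide 1 and -0.85 within slide 2. A family of 24 probes (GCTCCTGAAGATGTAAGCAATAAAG) had 16, 22 and 20 members called down on the 3 days, with medians of -0.53, -0.94 and -0.53. A family of 35 probes (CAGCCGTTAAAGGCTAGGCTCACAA) had 0 called at day 3, and 21 and 22 called down at day 7 and day 14, with medians of -0.43 and -0.45. The fry adjusted p on the 3 days was 0.00117, 0.000302 and 0.00445 for the family of 24. For the family of 35 the fry adjusted p was 0.600, 0.000896 and 0.000684. For both families camera gave an adjusted p = 0.979 with an estimated correlation on each day. None of the 80 tests gave a lower camera adjusted p with an estimated correlation, so that value is not particular to these families. The medians of both families on the days with calls were also below 0 under quantile normalization and normexp. The largest family, 503 bright probes with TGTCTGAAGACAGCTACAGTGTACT, had 4 members called up at day 3, 125 called down and 2 up at day 7 and 118 called down and 1 up at day 14. Its medians of 0.08, -0.03 and -0.09 on the 3 days were -0.05, -0.06 and 0.01 under quantile normalization, so the direction at day 3 and at day 14 turned with the scaling.

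The family of 127 probes shared 407 stretches of 15 bases, read on the opposite strand, with a family of 323 probes (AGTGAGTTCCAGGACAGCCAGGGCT). Those 323 had a median of 0.04 at day 3, which was -0.09 under quantile normalization and -0.03 within slide 1, with 2 called up and 3 called down. At day 14 their median was -0.30, with 1 called up and 108 called down. The difference between the strands was not tested.

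Probe pairs gave a check of how well separate probes read 1 sequence. Over 2648 pairs that overlap on the same strand, log2 fold changes correlated across pairs at 0.972 at day 3, 0.952 at day 7 and 0.932 at day 14. Both probes were called for 1203 pairs at day 3, 1079 at day 7 and 1086 at day 14, of which 0, 5 and 2 were called in opposite directions. Over 209 pairs on opposite strands the correlations were 0.197 (bootstrap interval 0.04 to 0.39), 0.142 and 0.106, and the last 2 intervals included 0. Both probes of 55, 33 and 36 such pairs were called on the 3 days, with 18, 8 and 11 in opposite directions.

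The surplus of falls among dim probes at day 14 against day 0 was weighed, with the test of the scaling chosen after the result was seen. Without a slide term the 15701 dimmest probes had a median log2 fold change of -0.49. Arrays of one day on different slides differed in the same direction: these probes were lower on slide 2 than slide 1 by a median of -0.31 at day 0 and at day 3, and on slide 3 than slide 2 by -0.10 at day 7. These predict -0.302 for day 14 against day 0, which is consistent with a slide difference as part of the cause. Scaling to the 75th percentile shifts all probes of an array alike. Without it the median was -0.641, and it ran from -0.91 to -0.49 when single arrays were left out. With all arrays the scaling thus made the median less negative. The unscaled median also holds the difference in brightness between arrays, so it does not tell whether the choice of percentile contributed. Quantile normalization left -0.09, but it gives every array 1 distribution and so does not tell the cause of the shift. With slide as a fixed block the median was -0.0461. It ran from -0.12 to 0.01 when single arrays other than day 7 replicate 1 were left out. An effect of time after injury and one of slide thus cannot be told apart, since day 14 meets the other slides through 1 array. The dimmest spike-in controls, E1A_r60_a104, E1A_r60_3 and E1A_r60_a107, were all lower on slides 2 and 3 than on slide 1. After scaling they differed between day 14 and day 0 by 0.35, -1.03 and -0.08. These few controls went both ways between the days, so the share of slide stays open.

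Other splits of the arrays were counted for each comparison. Within the 6 arrays of a pair of days, 1 of 10 splits, the real one, gave as many called probes in every comparison, which is too few splits for a share under 0.05. Fitted on those arrays alone, the real counts were 22725 for day 3 and 24993 for day 7 and 29126 for day 14 against day 0, 15200 for day 7 against day 3, 8529 for day 14 against day 7 and 32228 for day 14 against day 3, and the highest other split called 0 each time. For the F test over all 12 arrays, 1 of 100 splits, the real one, gave as many as 44660 called probes. The highest other gave 11786. Those splits moved arrays freely between slides, while the real days followed the slides in part, so they cannot separate time from slide. In 100 splits within slides, chosen after the first result was seen, the real one alone (1 of 100) gave as many, and the other 99 gave 0 to 39378, with a median of 24.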
